A study of Mus musculus with 6 samples.

How the data were processed

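Total RNA was extracted with Trizol from snap-frozen mammary tumours of F1 females and labelled with biotin by the Affymetrix protocol, per the labels' protocols. There were 3 samples of the AKR/J cross and 3 of the DBA/2J cross, each on 1 array, and the source names in the labels gave the groups. Replicate numbers only name the samples, in accession order.

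The deposited table holds log2 values for 22690 probe sets on each of the 6 arrays. MAS5 and RMA are both named, per the submitters' processing notes, with no version and no statement of which of them made these values. The log2 scale was read from the deposited values, which run from 3.65 to 14.73. Array medians were 7.57, 7.55 and 7.55 in AKR and 7.52, 7.55 and 7.53 in DBA F1 tumours, so the arrays lay at a common level as deposited. Their distributions were not identical: the SD of the values was 1.90, 1.76 and 1.91 on the AKR arrays and 1.98, 1.98 and 2.02 on the DBA arrays. This matters for the differences, whose median over probe sets of AKR minus DBA ran from 0.23 in decile 3 of mean level to -0.21 in decile 10. Whether background was subtracted, and how, is not given in the sources used here. No detection calls were used here, so a low value can lie at background, and differences of dim probe sets can be compressed.

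The 64 Affymetrix control probe sets were left out, which left 22626. Gene symbols came from the platform annotation: 20380 probe sets had 1 symbol, 691 had several and 1555 had none, and genes were named only from the first kind. The gene table of the mouse assembly GRCm38.p6 held 20351 of the first kind by gene identifier, 0 of them under another symbol, and was otherwise used only for chromosomes and older list symbols. Each of 12393 genes was represented by its probe set with the highest mean value over the 6 arrays, and disagreeing probe sets were reported for called genes. Of 122 named genes, 57 had more than 1 probe set, and in 14 of these another probe set had the opposite sign, none of which passed. These were probe sets of Ahr (0.06), Eif4e (0.39), Epb42 (-0.003), Gstm1 (0.22), H2-D1 (2.75), Hbb-b2 (-0.78), Mb (0.25), Myh11 (0.16), Pfkfb3 (0.41), Rrp1b (-0.13), Scd2 (0.80), Tlr4 (-0.52), Uty (-0.01) and Xist (1.90). Control probe sets at the ends of the Gapdh transcript gave differences of 3′ minus 5′ values of 0.05, 0.31 and 0.27 on the AKR arrays and 1.20, 0.12 and 0.75 on the DBA arrays (exact two-sided permutation p = 0.3).

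AKR and DBA F1 tumours were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all 22626 probe sets, adjusted p 0.05). Differences are AKR minus DBA, so a negative log2 value is higher in DBA F1 tumours. Errors given with ± are SDs over the 3 arrays of a cross. The gene lists, 26 in all, covered mammary epithelium, stroma, other cell types and processes, and were tested with limma's camera (two-sided, preset correlation 0.01, Benjamini-Hochberg over lists), with an estimated correlation and with fry as alternatives. Counts of members were adjusted over all probe sets and, separately, over the list alone. List means per array and correlations between arrays were compared with exact permutation tests over the 10 splits of the 6 arrays, which cannot give p below 0.1. Called genes were set against chromosomes with Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

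The lists and the rule for named genes were fixed before the data were examined. The rule's first part took up to 12 genes per direction whose brightest probe set passed and whose crosses did not overlap, which gave 7 genes. The next part took the 4 members of each list with the smallest p, and the last part took all measured members of the strain allele and the Y-linked and Xist lists together with Sipa1 and Rrp1b. A further gene of the rule is not reported here. In all 122 genes were named by it. Genes outside the rule (called probe sets that are not the brightest, further members of called lists, salivary gland, muscle, adipose and casein genes) were chosen after their values were seen.

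The test was run on simulated data made from these arrays' means and spread, with 200 of 22626 probe sets changed. It recovered 58% of changes of 1 log2 unit, 88% of 2, 90% of 3 and 100% of 5, with 10 false calls among 178. The measured data gave 22 calls, so their unadjusted cutoff was stricter than that of the simulation, and these shares can overstate what was recovered here. In a simulation in which 1 of 26 gene lists was shifted by 1 log2 unit, 2 were called, the shifted one and another.

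Results were also computed with quantile normalization, centring on the array median, only probe sets brighter than the median, Spearman correlation, the mean of a gene's probe sets in the lists, a trended and robust prior, array weights, 1 mean value per gene, an adjusted p of 0.10 and leaving out each array in turn. Lists of salivary gland genes were added after seeing the data. A setting also chosen after seeing the data left out AKR replicate 2, which holds salivary gland transcripts, and DBA replicate 1, which holds muscle and adipocyte transcripts, together.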

Results

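Gene expression was measured in 6 mammary tumour samples of female mice from 2 crosses. In both crosses 1 parent carried the PyMT transgene, the polyomavirus middle T antigen, which drives mammary tumours in mice. The other parent was the inbred strain AKR/J in 3 samples (AKR F1 tumours) and the inbred strain DBA/2J in the other 3 samples (DBA F1 tumours). The comparison asks which transcripts differ at baseline between tumours of the 2 genotypes. Total RNA of each tumour was hybridised to 1 Affymetrix array, and the deposited values are on the log2 scale. Array medians ran from 7.52 to 7.57 and the values of single probe sets from 3.65 to 14.73. Precision is limited by the 3 arrays per cross. The labels do not state that each sample came from a separate animal, so p-values measure the spread between these samples.

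All 30 measured members of the interferon response list lay higher in DBA F1 than in AKR F1 tumours. The list passed limma's camera test (adjusted p = 9.81e-19), with adjusted p = 0.693 with an estimated correlation. Ifi27l2a, an interferon-induced gene, lay at 10.60 ± 0.34 in DBA F1 tumours and 8.15 ± 0.09 in AKR F1 tumours (SD, n = 3 each), a 5.47-fold difference. Oas1a, an enzyme that senses double-stranded RNA, was 4.44-fold higher in DBA F1 tumours. In the other direction, the tight junction gene Cldn4 was 3.88-fold higher in AKR F1 tumours, at 10.09 ± 0.14 against 8.13 ± 0.36 (SD, n = 3 each). The RNA-binding protein gene Rbm47 was 4.21-fold higher in AKR F1 tumours.

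By limma, 22 of 22626 probe sets passed an adjusted p of 0.05, of which 8 were higher in AKR and 14 higher in DBA F1 tumours. These were 17 probe sets of 14 named genes, 1 probe set annotated to several genes and 4 without a gene name here. At an unadjusted p under 0.05 there were 5913 probe sets, against 1131 that chance gives on average, with 2921 higher in AKR and 2992 higher in DBA F1 tumours. The 3 values of a cross did not overlap those of the other cross in 39.2% of probe sets, where chance gives 10%. The number of calls was 1 without AKR replicate 1, 2 without AKR replicate 2, 11 without AKR replicate 3, 263 without DBA replicate 1 and 1 without DBA replicate 3. Without DBA replicate 2 it was 26, of which 19 were higher in AKR and 7 higher in DBA F1 tumours.

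Of the named genes, 7 were called at the brightest of their probe sets. The 4 that were higher in AKR F1 tumours were Rbm47 (log2 difference 2.08, SE 0.166, adjusted p = 0.0147 by limma), Cldn4 (1.96), the kinase gene Stk25 (1.81) and the cell surface gene Cd99 (1.41). The 3 that were higher in DBA F1 tumours were Ifi27l2a (log2 difference -2.45, SE 0.188, adjusted p = 0.0122 by limma), Oas1a (-2.15) and Kctd14 (-1.92). The limma adjusted p of Cldn4, Cd99, Oas1a and Kctd14 was 0.0392, and that of Stk25 was 0.0336. A further probe set of Kctd14 was also called (-1.63), whereas a dim further probe set of Rbm47, at 5.18 in AKR and 5.10 in DBA F1 tumours, differed by 0.08.

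The largest difference among the 22 calls came from a probe set of H2-D1, which encodes a classical MHC class I heavy chain. The H2-D1 probe set that differed most lay at 6.21 ± 0.02 in AKR F1 tumours and 11.69 ± 0.71 in DBA F1 tumours (SD, n = 3 each), a 44.4-fold difference. A pair of further H2-D1 probe sets were 23.1-fold and 16.6-fold higher in DBA F1 tumours. For these H2-D1 probe sets, a sequence variant of the strains cannot be told apart from a change in RNA level. Beta-2-microglobulin, the light chain of class I molecules, was called at a probe set of B2m that was 3.54-fold higher in DBA F1 tumours. The 4 probe sets without a gene name here were 30.6-fold, 12.8-fold, 7.02-fold and 2.65-fold higher in DBA F1 tumours, and the probe set annotated to several genes was 32.3-fold higher in AKR F1 tumours. Genes called only at a probe set other than their brightest were chosen after their values were seen.

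Probe sets of a single gene disagreed for several calls. The other H2-D1 probe sets ran from -1.92 to -0.43, except 1 that lay higher in AKR F1 tumours by 2.75 (limma adjusted p = 0.0684). The brightest H2-D1 probe set differed by -1.15 (limma adjusted p = 0.0837). For Sox4, a transcription factor gene, the called probe set differed by 3.74 between AKR and DBA F1 tumours, whereas the brightest Sox4 probe set differed by 0.09 and the rest by 0.64 to 0.82. For Nfic, the called probe set differed by 2.26 and the others by 0.58 to 0.94. For Lasp1, the called probe set differed by 1.60 and the others by -0.36 to 0.76. For Pdxdc1, the called probe set lay lower in AKR F1 tumours (-1.70), while the others lay higher by 0.35 to 0.84. For Ccng1, a cyclin gene, the probe sets went the same way, by -1.33 at the called one, -1.24 at the brightest and -0.84 at the remaining one.

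**Figure D1:**
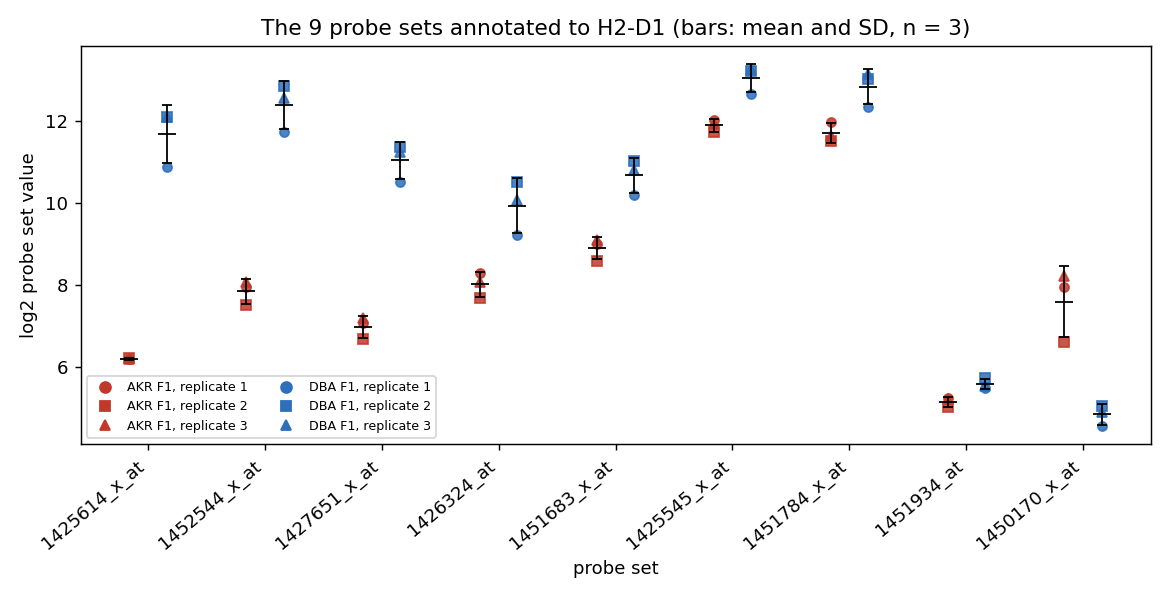
Log2 values of the 9 probe sets annotated to H2-D1 on the 3 AKR F1 and 3 DBA F1 arrays; points are arrays and bars give the mean and SD. The largest difference is -5.47 (AKR minus DBA), the brightest probe set differs by -1.15, and 1 probe set differs by 2.75 in the other direction.

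Among 26 gene lists, the interferon response list moved furthest when all arrays were used. Without DBA replicate 1 the skeletal muscle list moved further by its array means. These were 8.48, 8.29 and 9.59 in AKR F1 tumours, against 6.54 and 6.49 on DBA replicates 2 and 3. With all arrays, all 30 measured members of the interferon response list lay lower in AKR F1 tumours, with a median log2 difference of -1.39 and a mean of -1.50. The array mean of the list was 7.76 ± 0.13 in AKR and 9.26 ± 0.49 in DBA F1 tumours (SD, n = 3 each), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Its means on the DBA arrays were 8.75, 9.73 and 9.30, highest on replicates 2 and 3, on which the smooth muscle gene Acta2 also stood highest (13.26 and 12.13, against 10.37 on replicate 1). Over all probe sets 2 members passed, Ifi27l2a and Oas1a, and 26 passed adjusted over the list alone, all higher in DBA F1 tumours. These included the antiviral genes Oasl2 (8.5-fold), Usp18 (7.11 ± 0.29 against 9.83 ± 0.80) and Ifit3 (7.29 ± 0.13 against 9.83 ± 0.98), and Iigp1, an interferon-inducible GTPase (7.54 ± 0.61 against 10.72 ± 0.62; SD, n = 3 each). The antigen processing genes Tap1 (-1.72) and Psmb8 (-1.69) passed adjusted over the list alone, while Cxcl9 (-0.04) and Irf1 (-0.16) did not.

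The interferon response list passed limma's camera test with a preset correlation of 0.01 (adjusted p = 9.81e-19). The call was lost at adjusted p = 0.693 with an estimated correlation, and fry gave an adjusted p of 0.106. Macrophage markers (-0.19) and T and NK cell markers (0.10) had medians much nearer 0, and neither list passed. Values were spread less widely on the AKR arrays, with an SD of 1.86 ± 0.08 against 1.99 ± 0.02 on the DBA arrays (SD, n = 3 each; exact two-sided permutation p = 0.1). Without AKR replicate 2 the list had 24 members that passed adjusted over the list alone, without DBA replicate 1 it had 28, and without both, a setting chosen after seeing the data, 29.

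**Figure D2:**
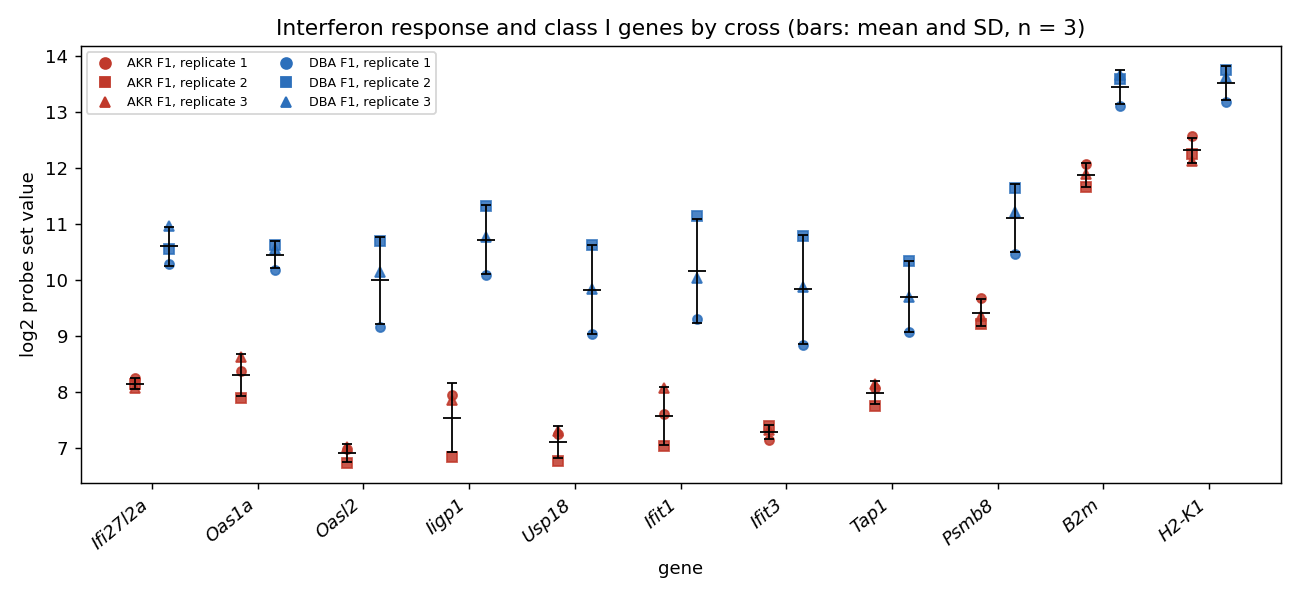
Log2 values of 9 interferon response genes and the class I genes B2m and H2-K1 on the 3 AKR F1 and 3 DBA F1 arrays; points are arrays and bars give the mean and SD. Every DBA F1 value of these genes lies above every AKR F1 value, as for Ifi27l2a (8.07 to 8.25 in AKR and 10.29 to 10.97 in DBA F1 tumours).

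Of 18 measured members of the MHC list, 13 lay lower in AKR F1 tumours (median -0.37), none passed over all probe sets at its brightest probe set, and 4 passed adjusted over the list alone. These were B2m (-1.57), the class I heavy chain genes H2-K1 (-1.21) and H2-D1 (-1.15), and H2-M3 (-0.74). For the heavy chain genes, a sequence variant under the probes cannot be told apart from a change in RNA level. The class II genes H2-Aa (-0.95), H2-Ab1 (-0.71) and Cd74 (-0.57) did not pass. The list passed limma's camera test (adjusted p = 0.0376), with adjusted p = 0.693 with an estimated correlation. It was lost without AKR replicate 3 (adjusted p = 0.0852 by limma) and without DBA replicate 3 (adjusted p = 0.06 by limma). Its median was -0.23 without AKR replicate 2, -0.57 without DBA replicate 2, -0.20 without DBA replicate 3 and -0.14 without AKR replicate 2 and DBA replicate 1.

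Genes of the hypoxia response and glycolysis lay lower in AKR F1 tumours in 23 of 24 measured members, with a median of -0.53. No member passed over all probe sets, and 5 passed adjusted over the list alone. They were Pdk1, a kinase that restrains pyruvate oxidation (8.40 ± 0.10 in AKR against 9.28 ± 0.17 in DBA F1 tumours), the glycolytic enzyme Pgk1 (-0.92), Pfkfb3 (-1.31), the mitophagy gene Bnip3 (-1.56) and Ero1a (-1.22). The list passed limma's camera test (adjusted p = 1.96e-05), with adjusted p = 0.961 with an estimated correlation. The array means of the list were 9.96, 9.48 and 9.80 in AKR and 10.05, 11.03 and 10.17 in DBA F1 tumours, so DBA replicate 2 stood highest. The count adjusted over the list alone was 2 without AKR replicate 1, 1 without AKR replicate 2, 1 without AKR replicate 3, 11 without DBA replicate 1 and 9 without both AKR replicate 2 and DBA replicate 1. The median of the list was -0.85 without DBA replicate 1 and -0.24 without DBA replicate 2.

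Immediate early and stress response genes lay lower in AKR F1 tumours in 21 of 28 measured members (median -0.38). No member passed over all probe sets, and 10 passed adjusted over the list alone, of which 9 were higher in DBA F1 tumours. The transcription factor gene Egr1 lay at 10.82 ± 0.21 in AKR and 11.94 ± 0.17 in DBA F1 tumours (SD, n = 3 each), and the mRNA decay factor gene Zfp36 differed by -0.98. The matricellular genes Ccn2 (-1.93) and Ccn1 (-1.27), Dusp1 (-1.60) and Fos (-1.15) went the same way, while Jun lay higher in AKR F1 tumours (0.53). The list passed limma's camera test (adjusted p = 0.00194), with adjusted p = 0.693 with an estimated correlation. The limma call was also lost among probe sets brighter than the median (adjusted p = 0.138). The count adjusted over the list alone was 4 without DBA replicate 1 and 2 without DBA replicate 3, and the median was -0.24 without AKR replicate 2 and also -0.24 without DBA replicate 3.

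Oxidative phosphorylation genes had a small median difference of -0.27, and 22 of 27 measured members lay lower in AKR F1 tumours. No member passed over all probe sets or adjusted over the list alone. The 4 members with the smallest p were Cycs, or cytochrome c (-0.67), the complex I genes Ndufs1 (-0.52) and Ndufa1 (-0.48), and the citrate cycle gene Idh3a (-0.47). The list passed limma's camera test (adjusted p = 0.00194), with adjusted p = 0.961 with an estimated correlation. The limma call was lost after quantile normalization (adjusted p = 0.616), among probe sets brighter than the median (adjusted p = 0.138) and without AKR replicate 2 and DBA replicate 1 together (adjusted p = 0.172). Its median was -0.16 without DBA replicate 1 and -0.10 without both arrays. The array mean of the list was 11.49 on DBA replicate 1, where muscle and fat transcripts stood highest, and at most 11.29 on the others. The brightest decile of all probe sets had a median difference of -0.21 and decile 3 one of 0.23.

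**Figure D3:**
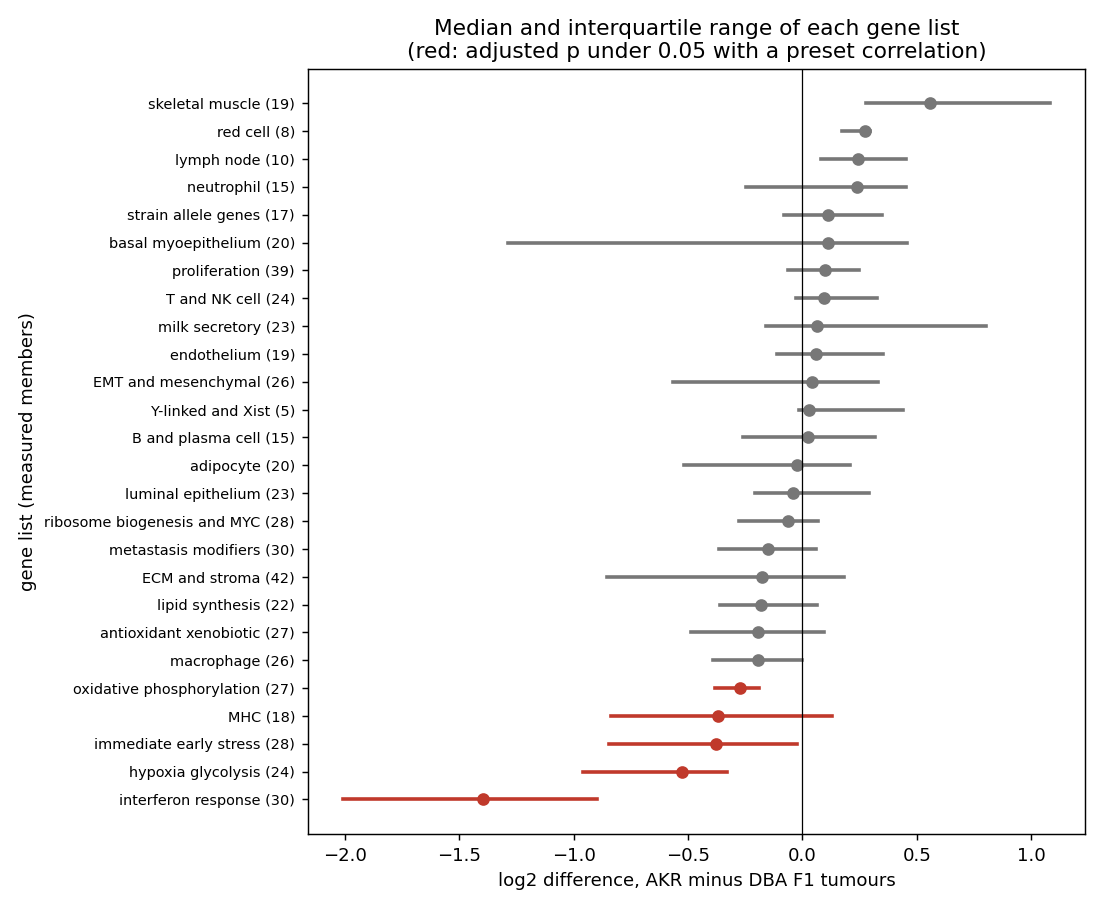
Log2 differences, AKR minus DBA F1 tumours, of 26 gene lists; points are medians, lines the interquartile range over members, and the measured members are in brackets. The 5 lists in red passed the camera test with a preset correlation, and the interferon response list has the lowest median (-1.39).

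Luminal epithelial markers had a median difference of -0.04, with 11 of 23 measured members higher in AKR F1 tumours. Cldn4 passed over all probe sets, and 3 members passed adjusted over the list alone, all higher in AKR F1 tumours. These were Cldn4, the claudin gene Cldn3 (12.50 ± 0.14 against 11.50 ± 0.35; SD, n = 3 each) and the epithelial transcription factor gene Elf3 (0.57), while the oestrogen receptor gene Esr1 (0.53, and 0.28 without AKR replicate 2) did not pass. In the milk and secretory list (median 0.06), the mucin gene Muc1 (-1.09) was the 1 of 23 members that passed adjusted over the list alone, and none passed over all probe sets. The milk protein gene Lalba (1.52), Olah (0.64) and the lipase gene Cel (1.11) did not pass, and Cel read 8.30, 8.16 and 6.52 on the DBA arrays. By limma's camera test the luminal list had an adjusted p of 0.567 and the milk list 0.959, and the milk list passed without AKR replicate 2 and DBA replicate 1 together (0.00185 by limma), higher in AKR F1 tumours.

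Basal and myoepithelial markers differed by a median of 0.11 but a mean of -0.29, since a few members lay far lower in AKR F1 tumours. The hemidesmosome integrin gene Itgb4 (0.82) was the 1 of 20 members that passed adjusted over the list alone, and none passed over all probe sets. The smooth muscle contraction genes Acta2 (-2.06), Mylk (-1.97) and Myh11 (-1.23) did not pass. Acta2 values on the DBA arrays were 10.37, 13.26 and 12.13, against 9.72 to 10.09 on the AKR arrays. The camera test of limma gave the list an adjusted p of 0.959. It gave 0.0444 without DBA replicate 1 and 0.019 without AKR replicate 2 as well, lower in AKR F1 tumours in both settings.

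In the mesenchymal list, the intermediate filament gene Vim lay at 10.48 ± 0.58 in AKR and 12.29 ± 0.56 in DBA F1 tumours (SD, n = 3 each), and the growth factor gene Tgfb1 lay higher in AKR F1 tumours (1.10). These were the 2 of 26 members that passed adjusted over the list alone, and none passed over all probe sets. Prrx1 (-1.76) and the polarity gene Crb3 (0.48) did not pass. The list had a median of 0.04, a mean of -0.20 and an adjusted p of 0.728 by limma's camera test. None of 42 extracellular matrix and stroma genes passed either count (median -0.18), with values of -1.60 for the basement membrane collagen gene Col4a1, -1.26 for the laminin gene Lamb1, -0.93 for Mmp3 and 0.70 for Col12a1. The camera test of limma gave this list an adjusted p of 0.0612, and 0.00746 without AKR replicate 1, 0.0299 without AKR replicate 3, 0.015 without DBA replicate 1 and 0.0062 without DBA replicate 2.

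No member of the immune, vascular or blood cell lists passed over all probe sets or adjusted over the list alone. Macrophage markers (26 measured, median -0.19) included the complement gene C1qa (0.54), C1qb (-0.58), Cd68 (-0.47) and the mannose receptor gene Mrc1 (-1.11). Neutrophil markers (15 measured, median 0.24) included S100a9 (-1.28), Mmp8 (0.53), Cxcr2 (0.56) and Mpo (0.49). T and NK cell markers (24 measured, median 0.10) included Cd4 (0.70), Zap70 (0.49), Cd3e (0.48) and Cd8b1 (0.32). B and plasma cell markers (15 measured, median 0.02) had a mean of -0.25 and included the coactivator gene Pou2af1 (-3.23), Jchain (-1.47), Fcer2a (0.47) and Pax5 (0.42). Jchain read 8.66, 5.69 and 8.29 on the DBA arrays, against 5.54 to 6.39 on the AKR arrays. Lymph node markers (10 measured, median 0.24), with Madcam1 at 0.55, Cd40 at 0.47 and Clec4g at 0.41, did not pass either. Without AKR replicate 2, C1qb differed by -0.23, Cd68 by -0.21, Mrc1 by -0.55, Fcer2a by 0.23, Madcam1 by 0.33 and Cd40 by 0.17.

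Endothelial markers (19 measured, median 0.06) included Plvap (0.47), Eng (0.49), Sox18 (0.53) and Emcn (-0.37), and red cell markers (8 measured, median 0.28) included Alas2 (-1.15), Epb42 (0.50), Hba-a2 (0.33) and Hbb-b2 (0.27). Epb42 differed by 0.26 without AKR replicate 2, and a dimmer probe set of Hbb-b2 differed by -0.78. Alas2 read 8.6, 9.6 and 7.6 on the DBA arrays, against 7.0 to 7.9 on the AKR arrays. In the order in which these 7 lists are named here, starting with macrophages, limma's camera test gave adjusted p of 0.267, 0.418, 0.253, 0.959, 0.256, 0.567 and 0.373. Without DBA replicate 1 the T and NK cell list (0.0411 by limma) and the lymph node list (0.0384 by limma) passed, higher in AKR F1 tumours. Both calls were lost without AKR replicate 2 as well (0.138 each by limma). After quantile normalization of all arrays the T and NK cell list lay lower in AKR F1 tumours (0.855 by limma), and the lymph node list had 0.82. The array means of both lists, 6.07 to 6.80, fall in deciles 3 and 4 of mean level, where all probe sets had medians of 0.23 and 0.20. Without DBA replicate 2 the macrophage list passed (0.00354 by limma), lower in AKR F1 tumours.

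Muscle and fat transcripts stood highest on the array of DBA replicate 1. Array means of the skeletal muscle list were 8.48, 8.29 and 9.59 in AKR F1 tumours and 11.31, 6.54 and 6.49 in DBA F1 tumours. The actin gene Acta1 (2.49), Tnnc2 (1.81), the creatine kinase gene Ckm (0.91) and the myoglobin gene Mb (-0.74) did not pass, nor did any of the 19 members over all probe sets or adjusted over the list alone. Adipocyte list means were 7.82, 7.86 and 7.82 in AKR and 9.16, 7.10 and 7.50 in DBA F1 tumours, and none of 20 members passed either count. Its members with the smallest p were Lipe (0.80), Acvr1c (0.28), Thrsp (-0.51) and the leptin gene Lep (0.35, and 0.14 without AKR replicate 2). Thrsp read 13.29, 12.22 and 12.67 on the DBA arrays, highest on that of replicate 1. By limma's camera test the muscle list had an adjusted p of 0.619 and the adipocyte list 0.959, and without DBA replicate 1 both passed, higher in AKR F1 tumours (3.38e-13 and 0.00789 by limma). These tests take a preset correlation of 0.01, while the correlation estimated over all 6 arrays was 0.983 for the muscle and 0.597 for the adipocyte list. With estimated correlations and all arrays, both lists had an adjusted p of 0.988 by limma's camera test.

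Salivary gland transcripts stood out on the array of AKR replicate 2, and these genes were chosen after their values were seen. Klk1, a kallikrein gene of salivary glands, read 11.57 there and at most 5.89 on the other arrays. Without that array, 26 of the 122 named genes had differences over 1.5 times smaller or of the opposite sign, and 2 had differences over 1.5 times larger. Control probe sets at the ends of the Gapdh transcript differed, 3′ minus 5′, by 0.21 ± 0.14 on the AKR and 0.69 ± 0.54 on the DBA arrays (SD, n = 3 each; exact two-sided permutation p = 0.3), with DBA replicate 1 highest at 1.20.

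**Figure D4:**
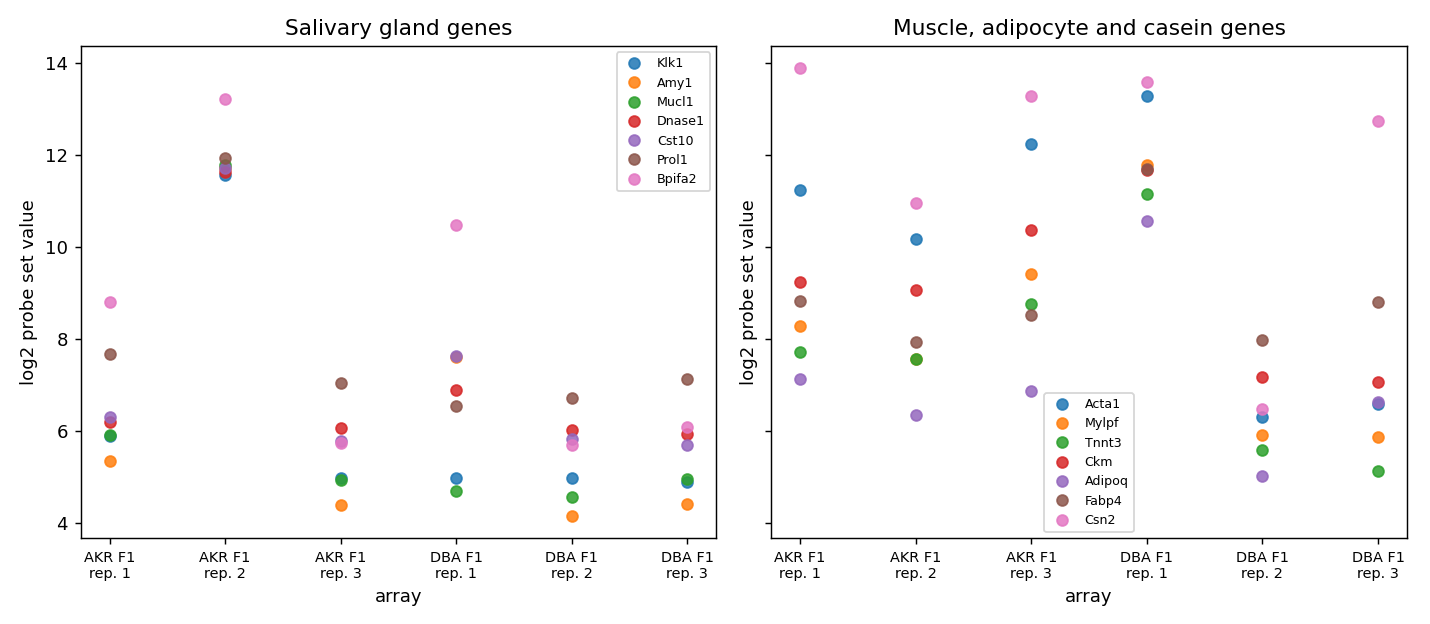
Log2 values on each of the 6 arrays of salivary gland genes (left) and of muscle, adipocyte and casein genes (right); each point is 1 array and 1 gene. Klk1 reads 11.57 on the array of AKR replicate 2 and at most 5.89 on the other arrays, and Adipoq reads 10.57 on that of DBA replicate 1 and at most 7.13 on the others.

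Proliferation genes did not separate the crosses. Of 39 measured members none passed over all probe sets or adjusted over the list alone (median 0.10), with values of 0.71 for Mybl2, 0.62 for the mitotic kinase gene Plk1, 0.47 for Cenpe and 0.39 for the thymidylate synthase gene Tyms (0.25 without AKR replicate 2). The same held for 28 ribosome biogenesis and MYC target genes (median -0.06), among them Eif4e (-0.63), Npm1 (-0.45), Nop58 (-0.42) and Rrp9 (0.44). It also held for 22 lipid synthesis genes (median -0.18), among them Scd2 (-0.65), Hmgcs1 (-0.64), Msmo1 (-0.64) and Srebf2 (0.49). The 27 antioxidant and xenobiotic genes (median -0.19) had values of -0.84 for the glutathione transferase gene Gstm1, 0.57 for Gstm3, -0.40 for Glo1 and -0.38 for Gstt1, and none passed either count. In that order limma's camera test gave adjusted p of 0.567, 0.235, 0.235 and 0.157. After quantile normalization the proliferation list passed (0.0378 by limma), and without AKR replicate 1 the ribosome biogenesis list passed (0.0427 by limma).

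Among 30 genes proposed as modifiers of metastasis, Arhgdib was the 1 that passed adjusted over the list alone (8.59 ± 0.14 in AKR against 9.26 ± 0.10 in DBA F1 tumours; SD, n = 3 each), and none passed over all probe sets. Vcam1 (-0.80), Cnot2 (-0.39) and Timp3 (-1.16, and -0.74 without AKR replicate 2) did not pass. Sipa1 (-0.03) and Rrp1b (0.06), which have been proposed as inherited modifiers in this tumour model, did not pass, and without AKR replicate 2 their values had the opposite sign (0.09 and -0.05). The list had a median of -0.15 and an adjusted p of 0.142 by limma's camera test, and 0.0384 without DBA replicate 1.

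None of 17 genes known for alleles that differ between inbred strains passed over all probe sets or adjusted over the list alone (median 0.11, adjusted p = 0.491 by limma's camera test). The complement C5 gene Hc, in which both AKR/J and DBA/2J carry a known loss-of-function allele, differed by 0.53, Gpnmb, mutated in DBA/2J, by 0.65 and Mx1 by -1.39. On the DBA arrays Mx1 read 6.51, 8.36 and 6.84, against 5.70 to 6.05 on the AKR arrays. The other members were Tyrp1 (0.82), Cdh23 (0.42), Glo1 (-0.40), Apoa2 (0.35), Ahr (-0.33), Pctp (0.31), the retrovirus restriction gene Fv1 (0.22), Tlr4 (0.15), Klrd1 (0.11), Myo5a (-0.10), Thy1 (-0.08), Slc11a1 (0.07), Alad (-0.03) and Gbp2b (-0.02). Without AKR replicate 2, Tyrp1 differed by 0.41, Cdh23 by 0.17, Apoa2 by 0.22, Ahr by -0.15, Tlr4 by 0.08, Klrd1 by 0.07, Myo5a by 0.05, Thy1 by 0.01, Slc11a1 by 0.35, Alad by 0.02 and Gbp2b by -0.09.

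The labels give female mice, and Xist, the transcript of the inactive X chromosome, was high on all arrays. The brightest Xist probe set lay at 11.18 ± 0.12 in AKR and 11.64 ± 0.05 in DBA F1 tumours (SD, n = 3 each), and it was the 1 of 5 list members that passed adjusted over the list alone, with none over all probe sets. A further Xist probe set differed the other way, by 1.90, and did not pass (adjusted p = 0.0837 by limma). Kdm5d (0.53), Uty (0.44), Eif2s3y (0.03) and Zfy2 (-0.01) did not pass (without AKR replicate 2, 0.30 for Kdm5d, 0.13 for Uty, 0.01 for Eif2s3y and 0.055 for Zfy2), and the list had an adjusted p of 0.959 by limma's camera test. Female mice carry no Y chromosome, so these Y-linked values lie at background, where differences of up to 0.53 arose. Dim markers elsewhere with differences of this size carry the same limit.

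The mean Pearson correlation across probe sets was 0.972 within crosses and 0.954 between them, a difference of 0.0184 (exact one-sided permutation p = 0.1, the smallest that the 10 splits allow). AKR replicates 1 and 3 were the most alike (0.992), and AKR replicate 2 had the lowest correlation, 0.915 with DBA replicate 3. DBA replicate 1 correlated with AKR replicate 3 (0.978) more than with DBA replicate 2 (0.962). The difference was 0.0094 without AKR replicate 2 (p = 0.2 by the same exact test), 0.0176 without DBA replicate 2 (exact p = 0.2), 0.012 without DBA replicate 3 and 0.0505 among probe sets brighter than the median. Probe sets are not independent replicates, so these correlations describe the arrays alone.

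The 7 genes called at their brightest probe set lay on 5 chromosomes. Of 20 chromosomes tested with Fisher's exact test, two-sided, none passed (smallest adjusted p = 0.14), where gene positions came from the mouse assembly GRCm38.p6. The called genes on chromosome 5 were Rbm47, Cldn4 and Oas1a.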

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

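The setting without AKR replicate 2 and DBA replicate 1 together was chosen after seeing the data. Against 22 calls (8 higher in AKR, 14 in DBA F1 tumours), limma gave 36 (15 and 21) after quantile normalization, 33 (11 and 22) after centring, 102 (31 and 71) among probe sets brighter than the median, 32 (12 and 20) with a trended and robust prior, 810 (300 and 510) at adjusted p 0.10, 657 (128 and 529) without both arrays and 1 (0 and 1) on 1 mean per gene, where 3208 genes had an unadjusted p under 0.05. Array weights gave 9969 (5739 and 4230), but their estimate did not converge and put a weight of 38.2 on AKR replicate 1, with 0.123 to 1.18 on the others. Leaving out 1 array gave 1 to 263 calls (0 to 28 higher in AKR, 1 to 235 in DBA F1 tumours), and without DBA replicate 2 most of the 26 calls (19) were higher in AKR F1 tumours. All 22 calls were kept after quantile normalization and centring, with the trended prior, without DBA replicate 1 and without both arrays, and 20 of them among brighter probe sets. Of the 22, 1 was kept without AKR replicate 1, 1 without AKR replicate 2, 9 without AKR replicate 3, 11 without DBA replicate 2 and 1 without DBA replicate 3. Apart from the smaller number of arrays or probe sets, the cause was not tested.

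Of 26 lists, 5 were called, against 3 among brighter probe sets, 8 without both arrays, 4 to 12 without 1 array, and 0 with limma's estimated correlation or fry (0 and 4 lists at an unadjusted p under 0.05). With an estimated correlation limma's adjusted p was 0.693 for interferon response, MHC and immediate early genes and 0.961 for hypoxia and oxidative phosphorylation. With fry it was 0.106 for the first 3 of these, 0.435 for hypoxia and 0.527 for oxidative phosphorylation. Immediate early genes (0.138) and oxidative phosphorylation (0.138) were lost among brighter probe sets, and oxidative phosphorylation also after quantile normalization (0.616) and without both arrays (0.172). Without 1 array the MHC list ran from 0.00354 to 0.0852 and the interferon mean difference from -1.76 to -1.26.

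Of 1298 values of named genes under quantile normalization, centring, the trended prior, brighter probe sets and left-out arrays (array weights, 1 mean per gene and adjusted p 0.10 were not tallied by gene), 1184 kept direction and side of the threshold, 31 lost their call, all without 1 array, 57 gained one and 26 reversed, none of a called gene. Reversed values belong to 11 genes, given as the range without 1 array: Alad -0.151 to 0.125 (0.13 after quantile normalization, 0.173 without both arrays), Eif2s3y -0.021 to 0.066 (quantile -0.007), Klrd1 -0.011 to 0.234 (quantile -0.052), Gbp2b -0.09 to 0.02, Slc11a1 -0.095 to 0.349, Mb -1.249 to 0.008, Myo5a -0.185 to 0.053 (both 0.057), Thy1 -0.26 to 0.071 (both 0.165), Zfy2 -0.066 to 0.055 (both 0.045), Sipa1 -0.099 to 0.089 (both 0.111) and Rrp1b -0.046 to 0.177 (both -0.031). The difference in correlation within and between crosses ran from 0.0094 to 0.0262 without 1 array and was 0.0505 among brighter probe sets, and no chromosome passed in any setting run. No paired analysis was possible because the labels give no shared replicate numbers. Other pseudocounts were not run, since the values are already log2. No background measure was used here, so what signal over background limits is open.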

Other observations

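The tests of single probe set size, of Pdxdc1, of the interferon list and of array quality were chosen after the results were seen, and so were the genes named in the next paragraphs.

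DBA replicates 2 and 3 shared transcripts that were low on the other arrays. Otor, which encodes a secreted cartilage and inner ear protein, read 11.44 and 9.87 on these arrays and 5.54 to 5.77 on the others. The cartilage genes Cnmd (10.75 and 10.62), Comp (10.55 and 10.08) and Col2a1 (11.32 and 9.67) also stood above the other arrays, where Cnmd read at most 6.72, Comp at most 7.77 and Col2a1 at most 8.30. Ecrg4 read 12.86 and 13.02 against at most 8.27, the transcription factor gene Olig1 9.19 and 10.30 against at most 5.63, and the cytokine gene Il17b 12.38 and 10.42 against at most 8.73. The smooth muscle genes Actg2 (9.42 and 8.29, others at most 6.22) and Myl9 (11.50 and 10.43, others at most 8.61) followed the same arrays. None of these genes passed between the crosses by limma (adjusted p 0.128 to 0.291).

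Single arrays also stood apart. On the array of DBA replicate 1, 14 of 12393 genes read over 2 log2 units above every other array, among them the adipocyte genes Adipoq (10.57, others at most 7.13) and Fabp4 (11.70, others at most 8.83) and the fast muscle genes Mylpf (11.78, others at most 9.41) and Tnnt3 (11.15, others at most 8.77). The casein gene Csn2 read 6.47 on the array of DBA replicate 2 and 10.97 to 13.88 on the others. On the array of AKR replicate 2 the number of such genes was 16, and on those of AKR replicates 1 and 3 it was 0.

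The 22 calls between the crosses compare with at most 0 by limma in the other splits of the 6 arrays (78 to 1519 probe sets at an unadjusted p under 0.05, against 5913), so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Sequence variants that each lie under a single probe set are argued against as the only source of the directions, over the set of 8 called genes with other bright probe sets. Of those probe sets, 84% (21 of 25) had the sign of the called one. The exact 95% interval, 63.9% to 95.5%, takes probe sets of a gene as independent, and 8 of the 25 were of Lasp1. Strain variants under several probe sets of a gene could shift them together, so the share cannot bear on these. The share gives no verdict on a single gene, and a sequence variant stays open for Pdxdc1 (0 of 2 with that sign), for Lasp1 (6 of 8, median 0.12 against 1.60) and for H2-D1, of which a dimmer probe set differed by 2.75. In 5 of these 8 genes (H2-D1, Sox4, Pdxdc1, Nfic and Lasp1), however, the called probe set moved over 1 log2 unit further than the median of the others, and a sequence variant or transcript form there cannot be told apart from a change in RNA level, since no probe sequences or strain genotypes were used here. An inherited difference in RNA level between the crosses stays open and untested.

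The interferon response list lay lower in AKR F1 tumours by a median of -1.39. The narrower spread of the AKR arrays is argued against as the whole cause, since the median was -1.305 after quantile normalization. None of 10000 random lists matched on mean level went as low (lowest -0.27). The list was picked for its shift, and random lists lack the correlation of its members, so that count is not a p-value. More macrophages in the DBA F1 tumours are argued against as the whole cause by 28 bright immune cell markers, 20 of them of macrophages. Their pooled median was -0.081, with 19 of the 28 lower in AKR F1 tumours, and 0 fell as low as the interferon list median. All 26 measured macrophage markers had a median of -0.19, with 19 lower in AKR F1 tumours. Without DBA replicate 2 the macrophage list passed limma's camera test (adjusted p = 0.00354), lower in AKR F1 tumours. The 95% bootstrap interval of the pooled median, -0.345 to -0.003, resamples markers and not tumours, and takes the markers as independent. With 4 markers of T and NK cells and 4 of B cells, lymphocytes were hardly covered. The dimmer Pou2af1 (-3.23) and Jchain (-1.47) were not among the 28, while 8 of all 15 B and plasma cell markers lay higher in AKR F1 tumours. Lymphocytes and rarer cell types stay open. The array with salivary gland transcripts is argued against by a median of -1.347 without it. An inherited difference in interferon signalling between the crosses may underlie the shift, as a hypothesis that was not tested, and so may infection, housing or tumour stage, on which the labels are silent. List means were 9.73 and 9.30 on DBA replicates 2 and 3, which shared cartilage and smooth muscle transcripts, 8.75 on replicate 1 and at most 7.84 on the AKR arrays. Tumour composition beyond the immune markers was not tested.

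On the array of AKR replicate 2, Klk1 read 11.57 (others at most 5.89), Mucl1 11.77 (others at most 5.91), Amy1 11.72 (others at most 7.60) and Bpifa2 13.21 (others at most 10.47), genes abundant in salivary glands. A poorer array that lifts dim probe sets is argued against as the whole cause of these readings. A list of 19 further salivary genes was made after the data were seen, though before their own values were looked at. The 10 dim genes among them were set apart later. Of these 10, 40% stood over 1 log2 unit above every other array (exact 95% interval 12.2% to 73.8%). Of 5147 equally dim other genes, 3.23% did so (two-sided Fisher's exact test, p = 0.000205). Some lifting stays open, since this array had the narrowest spread of values (SD 1.76) and only 1.51% of all 12364 other genes, bright ones included, stood as far above. Salivary gland tissue in that sample was tested with all 19 genes, of which 4 (Dnase1, Cst10, Crisp3 and Chrm1), or 21.1% (exact 95% interval 6.05% to 45.6%), stood over 1 log2 unit above every other array, against 1.51% of 12364 other genes (two-sided Fisher's exact test, p = 0.000177). These 4 genes are also those that stood out among the 10 dim ones, so the tests of dim genes and of all 19 are not separate evidence. The share of 21.1% fell between the bounds set beforehand for and against, and 9 of the 19 genes were also bright on the other arrays. Salivary tissue in the sample therefore stays a candidate source that cannot be told apart from salivary gland genes switched on in the tumour. The design gives no group that bears on it, and no biological explanation was tested.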
